A study of Sus scrofa with 5 samples.

How the data were processed

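Small RNA of exosomes, the nanometre-sized vesicles that cells release into body fluids, was sequenced from serum, plasma, semen, urine and bile of Rongchang pigs, a Chinese breed, at postnatal day 180. There was 1 library per fluid. Per the labels' protocols, exosomes were collected with a commercial isolation reagent and RNA was extracted with Trizol. Small RNA was then size-selected by polyacrylamide gel electrophoresis, ligated to adaptors, reverse transcribed, amplified and sequenced. The labels name 2 different Illumina instruments. How many animals gave each fluid, and whether the fluids came from the same animals, is not given in the sources used here.

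For each library the authors deposited a table of 411 mature miRNA names (prefix ssc-, left out below), each with a read count. Per the submitters' processing notes, bcl2fastq 2.17 was used and the genome build was Sscrofa10.2. The aligner, the miRNA annotation and the rule for reads that match several miRNAs are not given in the sources used here. Values of members with nearly the same or closely related sequence are therefore uncertain. They include the let-7 family, miR-10a-5p and miR-10b, miR-199a-3p and miR-199b-3p, miR-378 and miR-378b-3p, and miR-192 and miR-215. Tested on the files, every deposited count was 0 or at least 10 in all 5 libraries. A value listed at 0 therefore stands for 0 to 9 reads, and no upper limit from a listed 0 was computed, except that the 5p arm of miR-148a in urine was taken as 9 reads where its share is compared between fluids. The same tables hold a second column that the header calls normalized. The values fit RPM (reads scaled to a library total of 1000000), which the authors computed against a library total larger than the sum of the miRNA counts. Dividing counts by RPM gave 1 constant per library, with no value off by more than 0.1%, so this total could be recovered. Which reads the total counts is not given in the sources used here. The 411 names do not hold every pig miRNA, and names outside them were not analysed here. Gene coordinates were not used, because the annotation at hand was of another genome build.

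From the counts, the share of each miRNA in its library's miRNA counts was computed as a percent and as CPM (counts scaled to a miRNA total of 1000000). Shares carry exact Clopper-Pearson 95% intervals, and ratios of CPM between libraries carry exact conditional binomial 95% intervals. The protocol names no molecular identifiers, so these intervals cover counting error only and leave out the variation between animals, collections and library preparations. With 1 library per fluid no difference between fluids has a replicate check, and no p-value is given. No paired or blocked fit could be made for the same reason. All comparisons were described by fixed rules of size.

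The choices below were made before the data were examined, except where stated. A miRNA was detected in a fluid at 3 or more counts. It was enriched in a fluid if it had at least 100 counts there and a CPM at least 4 times the highest CPM of the other 4 fluids. The floor for low counts in that ratio was planned at 3 counts. Because the files list nothing under 10, the floor was raised to 10, so that a ratio against a listed 0 is a lower bound apart from counting error, and 3 became an alternative. Serum and plasma were compared over miRNAs with at least 100 counts in either, with 2-fold as the limit. Similarity was Spearman's rho across the miRNAs with at least 10 counts in at least 1 library. Its 95% interval was taken from 1000 bootstrap draws of miRNAs. Lists of miRNAs known from blood cells, organs or genomic clusters were scored by the median over members of log2(CPM + 1) in a fluid minus the mean over the other 4. That median was given a percentile among 10000 random lists of the same size, matched on mean expression in 5 groups. The percentile describes these libraries and is no test. All arms listed under a name counted as members, and members needed at least 10 counts in at least 1 library.

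The miRNAs named in the text were set by rule. They are the 10 most abundant of each fluid, the 5 enriched miRNAs with the largest ratio per fluid and the 5 with the largest ratio in each direction between serum and plasma. In each list the 2 most abundant members in the fluid of its highest share were also named. Other names are said to have been chosen after their values were seen.

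Alternatives were edgeR 4.0.16 TMM library sizes, DESeq2 1.42.0 size factors, totals without the most abundant miRNA, other minimum counts, ratios and pseudocounts, summed arms, and thinning of every library to 26522 counts. Added after the data were seen were the authors' RPM, the floor of 3 counts, thinning with counts under 10 set to 0, values listed at 0 taken as 10 counts, totals without the plasma-enriched miRNAs, the urine or the plasma library left out, and the direction of each list's sum and members under each scaling. edgeR and DESeq2 gave scaling factors only. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3. The enrichment rule was tested on simulated data of 237 miRNAs at the 5 real depths, with 40 miRNAs raised 8-fold or 16-fold in 1 fluid each. Of the 16 raised 8-fold that reached 100 counts it found 10, and of the 19 raised 16-fold it found 17. Recovery differed by fluid: of 4 miRNAs raised 8-fold with 100 counts it found 4 in serum, 3 in plasma, 3 in semen and 0 in bile, and in urine none of those raised 8-fold reached 100 counts. The numbers of enriched miRNAs are therefore not equally complete across fluids. The rule called no unchanged miRNA. Apart from the raised miRNAs, however, the simulated libraries were drawn from a common profile. False calls from the different compositions of the real libraries were therefore not tested. All 27 that reached 100 counts and whose simulated ratio, with the floor applied, was at least 5 were found. Raised miRNAs under 100 counts, which the rule cannot call, are not among these 27. The floor of 10 counts is 377 CPM in urine and 4.38 to 21.1 CPM in the other fluids.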

Results

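Exosomal miRNAs were profiled in 5 body fluids of pigs aged 180 days, to describe the miRNA content of each fluid. The libraries held 473168 miRNA counts in serum, 1153755 in plasma, 2284926 in semen, 26522 in urine and 1673239 in bile. Set against the library totals recovered from the authors' RPM, which were 10593418 reads in serum, 7207788 in plasma, 10801967 in semen, 10796774 in urine and 10555126 in bile, the listed miRNAs took 4.47% of the serum library (95% interval 4.45 to 4.48), 16.01% of plasma (15.98 to 16.03), 21.15% of semen (21.13 to 21.18) and 15.85% of bile (15.83 to 15.87). In urine they took 0.246% (0.243 to 0.249). The urine library had the fewest miRNA counts, and 26 miRNAs reached 100 counts in it, against 86 to 115 in the other fluids. Each fluid was measured in 1 library, so the differences below are differences between libraries, with intervals for counting error only.

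The first question was which miRNAs each fluid carries and which are shared. Of the 411 listed miRNAs, 237 were detected in at least 1 fluid. Serum held 180, bile 179, semen 174, plasma 161 and urine 84. A core of 67 miRNAs, 28.3% of those detected, was present in all 5 fluids, and 37 were detected in a single fluid. The core took 82.4% of the counts in serum, 92.8% in plasma, 98.3% in semen, 97.2% in urine and 98.3% in bile. Among the single-fluid miRNAs, miR-199b-3p was listed in bile alone with 1584 counts, and miR-34c, a miRNA known from male germ cells, in semen alone with 604. miR-199b-3p has nearly the sequence of miR-199a-3p, which was listed in all 5 fluids, and how their reads were assigned was not checked, so its place among the single-fluid miRNAs is uncertain. miR-7137-3p was found in plasma alone with 272 counts and miR-2320-3p in serum alone with 133. The only single-fluid miRNA of urine was miR-1285 with 36 counts. These 5, the most abundant single-fluid miRNA of each fluid, were chosen after their values were seen. Depth set part of the numbers: with every library thinned to 26522 counts and counts under 10 set to 0 as in the files, a median of 91 miRNAs remained in serum, 63 in bile, 61 in semen and 50 in plasma, beside the 84 of urine, and the shared core was 23. Without the urine library 104 miRNAs were common to the other 4 fluids.

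A small number of miRNAs made up most of each library. The 10 most abundant took 64.8% of the counts in serum (64.7 to 65.0), 93.1% in plasma (93.1 to 93.2), 89.1% in semen (89.1 to 89.2), 78.0% in urine (77.5 to 78.5) and 84.4% in bile (84.4 to 84.5). Together these top lists named 26 miRNAs. miR-148a-3p, a miRNA abundant in liver, and miR-99a stood in the top 10 of all 5 fluids. miR-148a-3p was the most abundant miRNA of semen with 52.8%, of bile with 32.1% and of serum with 18.1%, and held 16.6% in urine, but 1.41% in plasma. miR-99a held 4.89% in serum, 4.95% in semen, 4.09% in urine, 2.54% in bile and 0.593% in plasma. miR-21, let-7f and let-7i were in the top 10 of every fluid except plasma, and let-7g in those of serum, urine and bile.

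The remaining leading miRNAs differed by fluid. In serum they were miR-451, which is made in red blood cells, with 8.48%, miR-140-3p with 8.13%, miR-92a with 3.26% and miR-215 with 2.95%. In plasma 3 miRNAs took 83.9% of all counts (83.8 to 84.0): miR-378 with 41.4%, miR-320 with 25.6% and miR-423-5p with 16.9%. They were followed by miR-296-3p with 3.02%, miR-378b-3p with 1.60%, miR-9820-5p with 1.10%, miR-122 with 1.03% and miR-22-3p with 0.497%. Semen was led, after miR-148a-3p, by miR-21 with 8.69%, miR-10a-5p with 5.33% and miR-10b with 4.98%, a pair encoded within the HOX gene clusters. miR-26a held 3.29% there, let-7a 2.35% and let-7c 1.76%. In urine miR-30a-5p was first with 22.1% (21.6 to 22.6), and miR-10b held 12.0%, miR-10a-5p 4.63% and miR-26a 4.25%. In bile miR-192 held 13.7%, the liver miRNA miR-122 5.47%, miR-143-3p 2.27% and miR-30a-5p 1.94%.

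**Figure D1:**
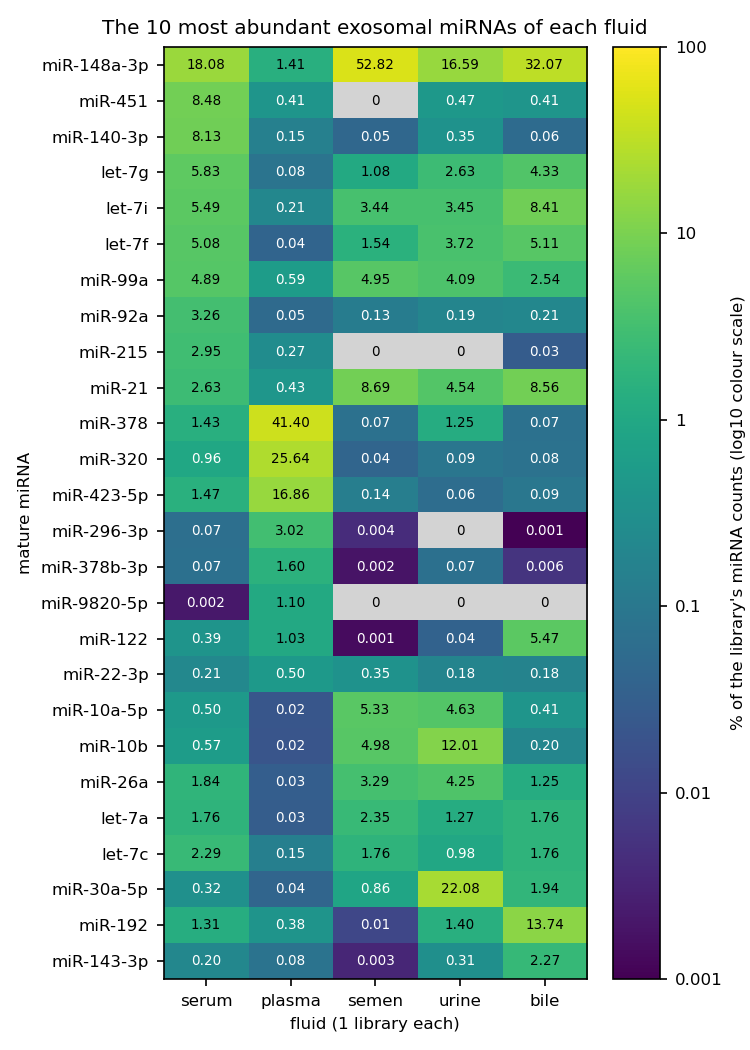
Heat map of the 26 miRNAs that stood among the 10 most abundant of at least 1 fluid (rows) in the 5 libraries (columns). Numbers give the percent of the library's miRNA counts and colours the same value on a log10 scale, with grey for values listed at 0. miR-148a-3p is high in serum, semen, urine and bile, whereas plasma is filled by miR-378, miR-320 and miR-423-5p.

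The overall similarity of the fluids was compared for all 10 pairs across the same 237 miRNAs, which are not independent replicates. Urine and bile had the highest Spearman's rho, 0.70 (bootstrap interval 0.62 to 0.77), followed by serum and bile with 0.69 (0.62 to 0.76) and serum and plasma with 0.67 (0.58 to 0.74). These intervals overlap, so the order of these pairs is not resolved. Without the filter on low counts serum and bile had the highest rho, 0.80, and urine and bile had 0.69, below 4 other pairs. At 100 or more counts in at least 1 library urine and bile had 0.76, followed by semen and urine with 0.65. Urine listed 84 of the 237 miRNAs and the rest were tied at 0 there, so its rho values partly reflect which miRNAs were listed. The lowest values were those of plasma with semen, 0.34 (0.20 to 0.45), with urine, 0.43 (0.32 to 0.53), and with bile, 0.46 (0.34 to 0.55). Their order is not resolved either, and without the filter on low counts plasma and urine had the lowest rho, 0.55, against 0.58 for plasma and semen. The interval of serum and plasma lay above those of plasma with each of semen, urine and bile.

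The next comparison asked which miRNAs were concentrated in a single fluid, at 4 or more times the CPM of every other fluid. By that rule 13 miRNAs were enriched in serum, 7 in plasma, 7 in urine, 4 in bile and 2 in semen. The counts are limited by urine, where a listed 0 had to be read as 377 CPM and where some miRNAs were abundant themselves. Without the urine library they were 29 in serum, 16 in plasma, 11 in bile and 8 in semen. Some of the miRNAs gained had counts in urine, such as miR-10b with 3184 and miR-10a-5p with 1229 for semen, and miR-1 with 174 for bile.

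Of the 13 serum-enriched miRNAs, miR-23a had the largest ratio with the floor applied. It stood at 12452 CPM, 27.5 times its level in urine, the next highest fluid (95% interval 15.7 to 53.3), from 12 urine counts. miR-140-3p was 23.4 times (19.1 to 29.1) and miR-451 18.1 times (15.2 to 21.8) their levels in urine, and miR-92a was 15.7 times its level in bile (15.1 to 16.3). miR-342, known from lymphocytes, was at 6277 CPM and at least 16.6 times the next fluid with urine at its floor (9.04 at the lower end of the counting interval). Its ratio is a lower bound, so its rank against miR-23a is not resolved. Without the urine library miR-342 had the largest ratio in serum, 219 times bile (165 to 297), and miR-23a came to 30.5 times plasma (27.8 to 33.6). The other serum-enriched miRNAs included miR-486, an erythroid miRNA, at 10.4 times its plasma level (9.94 to 11.0), and miR-150, a lymphocyte miRNA, at least 5.65 times the next fluid on the same terms (lower end 3.06, under the limit of 4). This pair was chosen after its values were seen. Only part of the 13 passed under other scalings: 6 with TMM and 5 with DESeq2 size factors, miR-140-3p, miR-342 and miR-92a among them in both. With these 2 scalings miR-23a came to 3.09 and 2.99 times, miR-451 to 2.07 and 2.01 times and miR-486 to 1.06 and 1.03 times their plasma levels. With totals without the most abundant miRNA 12 passed, and on the authors' RPM 7. On the authors' RPM miR-23a came to 8.51 times, miR-451 to 5.72 times and miR-486 to 2.92 times plasma.

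Of the 7 plasma-enriched miRNAs, 6 were among the 10 most abundant of that library. miR-296-3p stood 44.4 times (39.8 to 49.8), miR-378 28.9 times (28.2 to 29.6), miR-320 26.7 times (25.9 to 27.5) and miR-378b-3p 22.4 times (20.1 to 25.0) above serum, the next highest fluid in each case. miR-9820-5p had 12740 counts in plasma, 10 in serum and was listed at 0 in the other fluids, at least 29.3 times the next fluid with urine at its floor (lower end of the interval 15.9). miR-423-5p, at 11.5 times serum (11.2 to 11.8), and miR-671-5p, at least 4.50 times the next fluid (lower end 2.44, under the limit of 4), completed the set. All 7 also passed under TMM, DESeq2 size factors, totals without the most abundant miRNA and the authors' RPM, but the ratios depended strongly on the scaling: with TMM miR-296-3p came to 439 times, miR-378 to 285 times and miR-423-5p to 113 times serum, and on the authors' RPM to 159, 104 and 41.2 times. miR-378b-3p has nearly the sequence of miR-378, and reads from either could have been counted for the other.

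Semen was enriched in miR-135, with 6200 counts there and at least 7.197 times the next fluid with urine at its floor (lower end of the interval 3.91, under the limit of 4), and in miR-210, a hypoxia-induced miRNA, at 5.20 times its level in urine (2.97 to 10.1). Without the urine library miR-676-3p, at 27.3 times serum (18.3 to 42.7), and miR-34c, at least 12.5 times the next fluid (lower end 6.75), were also enriched. So were miR-10a-5p, at 10.6 times serum (10.1 to 11.0), and miR-10b, at 8.75 times serum (8.42 to 9.09). All of these were chosen after their values were seen. Urine itself held miR-10b at 120051 CPM, above the 49776 CPM of semen, and miR-10a-5p at 46339 CPM, near the 53277 CPM of semen. miR-210 came to 2.41 times plasma with TMM and 2.49 times with DESeq2 size factors. In urine, miR-204, a miRNA of kidney epithelium, was 30.3 times its bile level (24.3 to 37.7), from 125 counts. miR-363 was 12.8 times its serum level (10.4 to 15.6) and miR-206, a skeletal muscle miRNA, 7.84 times (6.23 to 9.82). Both arms of miR-30a were higher than in bile, miR-30a-5p by 11.4 times (11.1 to 11.7) and miR-30a-3p by 9.06 times (7.85 to 10.4). These urine values are relative to the other miRNAs of the library: on the authors' RPM, where all urine miRNAs are scarce, each of these 5 stood below the next fluid, and no miRNA was enriched in urine. miR-206 was also level with plasma under TMM, at 1.003 times, and at 1.36 times with DESeq2 size factors.

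Bile was enriched in miR-192, at 137441 CPM and 9.83 times its urine level (8.87 to 10.9), in miR-143-3p, a smooth muscle miRNA, at 7.34 times urine (5.91 to 9.22), in miR-199a-3p, a fibroblast miRNA, at 6.53 times serum (5.82 to 7.36), and in miR-122, at 5.33 times plasma (5.23 to 5.43). The direction for miR-122 depended on the scaling of the plasma library, since it became 0.80 times with DESeq2 size factors and 1.03 times with TMM. miR-199a-3p came to 1.67 times plasma with TMM and 1.31 times with DESeq2 size factors. Without the urine library miR-194a, which is transcribed with miR-192 or its relative miR-215, was also enriched in bile, with 7450 counts and 75.2 times its serum level (52.0 to 113); it was chosen after its values were seen.

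Serum and plasma come from the same compartment, plasma with its clotting factors kept and serum after clotting. Among 119 miRNAs with at least 100 counts in either, 87 were at least 2-fold higher in serum and 24 at least 2-fold higher in plasma. Thus 93.3% of them differed by 2-fold, against 51.4% to 88.7% in the other 9 pairs of fluids, but this order depended on the shift described next. Relative to each pair's median ratio, among miRNAs above 0 in both, 69.7% differed between serum and plasma. More differed between plasma and semen (87.0%), plasma and bile (76.6%), serum and bile (75.8%) and serum and semen (75.4%). Plasma and urine were level with serum and plasma (69.6%). Fewer differed between semen and bile (65.2%), urine and bile (62.2%), serum and urine (54.8%) and semen and urine (50.7%). Serum and plasma thus lay mid-rank, and the pairs rest on unequal sets of 56 to 124 miRNAs. The median log2 ratio of plasma to serum was -2.77, and this shift moved with the scaling, to 0.53 with TMM, 0.57 with DESeq2 size factors and -0.93 on the authors' RPM. Under both TMM and DESeq2 size factors 52 miRNAs were 2-fold higher in plasma and 34 in serum, so that plasma held 60.5% of the differing miRNAs in place of 21.6%. Relative to the median ratio, 43 were higher in plasma and 43 in serum, and the remaining 33 lay within 2-fold of it. Centring on the median makes the numbers on its sides similar by construction, so their balance is no result.

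The miRNAs furthest towards plasma were miR-9820-5p at 522 times its serum level (284 to 1090), miR-671-5p at 80.2 times (43.5 to 168), miR-127 at 53.9 times (31.4 to 101), miR-296-3p at 44.4 times and miR-378 at 28.9 times. The first 3 rest on 10, 10 and 13 counts in serum. miR-127 lies in the imprinted DLK1-DIO3 locus. Furthest towards serum were miR-342 at 362 times its plasma level (234 to 594), miR-30c-5p at 135 times (80.2 to 249), miR-182 at 135 times (104 to 177), miR-139-5p at 133 times (80.1 to 239), and miR-574, listed at 0 in plasma, at least 132 times (lower end 71.2). All 10 kept their direction under every alternative in which they could be measured, but their size moved with the scaling. On the log2 scale of plasma over serum, miR-342 went from -8.50 to -5.20 with TMM, miR-30c-5p from -7.08 to -3.78 and miR-378 from 4.85 to 8.16. miR-122 was higher in plasma, 10259 against 3893 CPM, and miR-451 was higher in serum, 84805 against 4139 CPM.

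**Figure D2:**
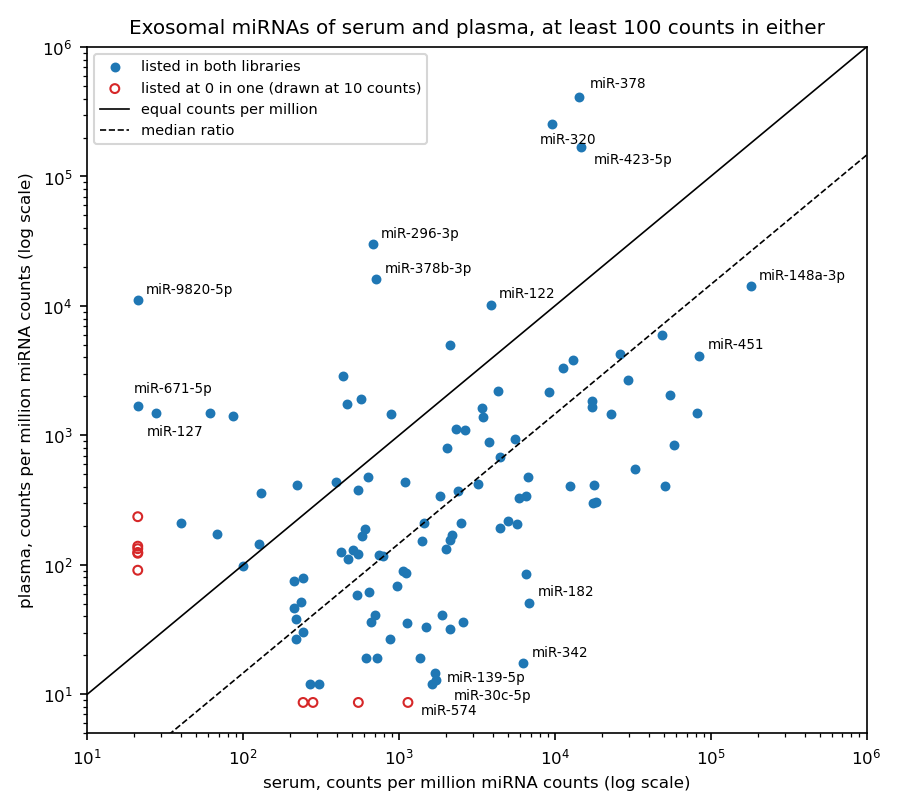
Scatter plot of serum (x axis) against plasma (y axis) CPM, both on log scales, for the 119 miRNAs with at least 100 counts in either library. Filled points are listed in both libraries and open points are listed at 0 in one and drawn at 10 counts; the solid line marks equal CPM and the dashed line the median ratio of -2.77 on the log2 scale. miR-378, miR-320 and miR-423-5p lie far above both lines, and most miRNAs below the solid line.

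The 14 lists asked whether miRNAs of known cell types, organs or clusters stood apart in a fluid. Of the 70 combinations of list and fluid, 15 lay outside the central 95% of random lists, where 3.5 would be expected by chance for independent lists; the lists share members and arms. Serum stood apart for the erythrocyte and leukocyte lists. Their matched random lists also lay above 0 in serum, at median log2 differences of 2.26 and 2.86, so part of each difference below is not particular to the list. A listed 0 entered as 0 CPM, which can enlarge the serum difference. In urine 3 erythrocyte and 2 leukocyte members were listed above 0. All 9 measured members of the erythrocyte list were above their mean in the other fluids and 8 were highest in serum, the exception being miR-363, which was highest in urine (median log2 difference 4.66, percentile 99.6). The list took 14.2% of serum counts and 0.876% of plasma counts, led by miR-451 and miR-92a. With TMM or DESeq2 size factors its sum was still highest in serum, at 1.65 and 1.59 times plasma, but 5 of the 9 members were highest there. All 9 members of the leukocyte list were highest in serum (6.11, percentile 99.9), led by miR-146a-5p with 1.12% and miR-342 with 0.628%, and the list was low in semen (-4.81, percentile 0.55). Which blood fluid held more of it depended on the scaling: with TMM and DESeq2 size factors 5 members were highest in serum and 4 in plasma, and the sum was 1.56 and 1.61 times higher in plasma through miR-146a-5p. The miR-17-92 cluster and its paralogs, tied to cell proliferation, were high in serum (4.66, percentile 99.8), with 9 of 12 members highest there, led by miR-92a and miR-20a; 2 of its members are also in the erythrocyte list, 6 members were highest in serum with TMM or DESeq2 size factors, and without the plasma library its percentile was 95.1. The platelet list did not stand apart in any fluid. Its sum was highest in serum, but in plasma with TMM or DESeq2 size factors and in semen on the authors' RPM. In serum its median difference was 1.76 (percentile 35.0), and its leading members were miR-24-3p with 1.73% and miR-191 with 0.654%.

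The kidney list stood apart in urine, where 11 of its 15 members were highest (3.55, percentile 100). It took 44.8% of urine counts (44.2 to 45.4), led by miR-30a-5p and miR-10b, against 12.9% in semen, 3.75% in serum, 3.44% in bile and 0.152% in plasma. It was low in plasma (-5.04, percentile 0.04) and in serum (-0.31, percentile 0.11, but 5.46 without the urine library). As a part of the whole library urine no longer led. On the authors' RPM scale the list came to 2.73% of semen, 0.545% of bile, 0.167% of serum, 0.110% of urine and 0.0244% of plasma. In bile the hepatocyte list was high (3.65, percentile 99.9), with 7 of 8 members above their mean elsewhere, although 3 of 9 alternatives placed it inside the range, down to percentile 93.3. Its summed share was similar in semen, 53.0%, and bile, 51.8%. With TMM the sum was higher in bile, by 1.06 times. It was higher in semen by 1.24 times with DESeq2 size factors and 1.37 times on the authors' RPM. In semen the median was low (-3.22, percentile 0.54): miR-148a-3p and miR-148a-5p made up nearly all of the sum, and miR-122 and miR-192 were at 0.00140% and 0.0118%. The stromal list was high in bile (4.77, percentile 100) and low in semen (-3.71, percentile 0.07), led by miR-21 with 8.56% and miR-143-3p with 2.27% in bile. The sum was similar in semen on the authors' RPM, 1.84% of the library against 1.81% in bile, from miR-21.

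The let-7 family, regulators of developmental timing, was low in plasma (-5.10, percentile 1.22), where none of the 9 members exceeded its mean elsewhere. It took 0.517% of plasma counts, 20.8% of serum, 10.4% of semen, 12.3% of urine and 21.7% of bile, led there by let-7i and let-7f; on the authors' RPM the plasma sum, 0.0827% of the library, lay above that of urine, 0.0303%. In bile its percentile was 97.7, but it stayed past the range in only 6 of 9 alternatives and was 87.8 without the plasma library. The muscle list was low in semen (-4.03, percentile 0.34), although 3 of 9 alternatives placed it inside the range. Its leading members were miR-1 with 0.656% and miR-206 with 0.426% of urine counts. Of the 15 names of the male germline list 2 were measured, miR-34c and miR-202-5p, and the other 13 were not analysed here. Both were listed in semen alone, with 604 and 11 counts, and passed the filter on low counts through semen alone, so that the percentile there (98.6, but 94.0 without the filter) carries little weight, although it is counted among the 15 combinations. The neural list and the DLK1-DIO3 list did not stand apart. The neural list was led in serum by miR-128, at 0.251%, and miR-129b, at 0.00867%. Its sum was highest in plasma under TMM, DESeq2 size factors and the authors' RPM. The DLK1-DIO3 list, led by miR-127 and miR-370, had 3 measured members, all highest in plasma (percentile 92.5). Of its 47 names 17 were among the listed miRNAs. miR-370 and miR-382 were listed in plasma alone, with 44 and 35 counts. They passed the filter on low counts through plasma alone, so they could be highest only there. miR-127 was also listed in serum, urine and bile. The epithelial list had 2 measured members, miR-429 and miR-205, and the pancreas list 1, miR-7, and neither stood apart.

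**Figure D3:**
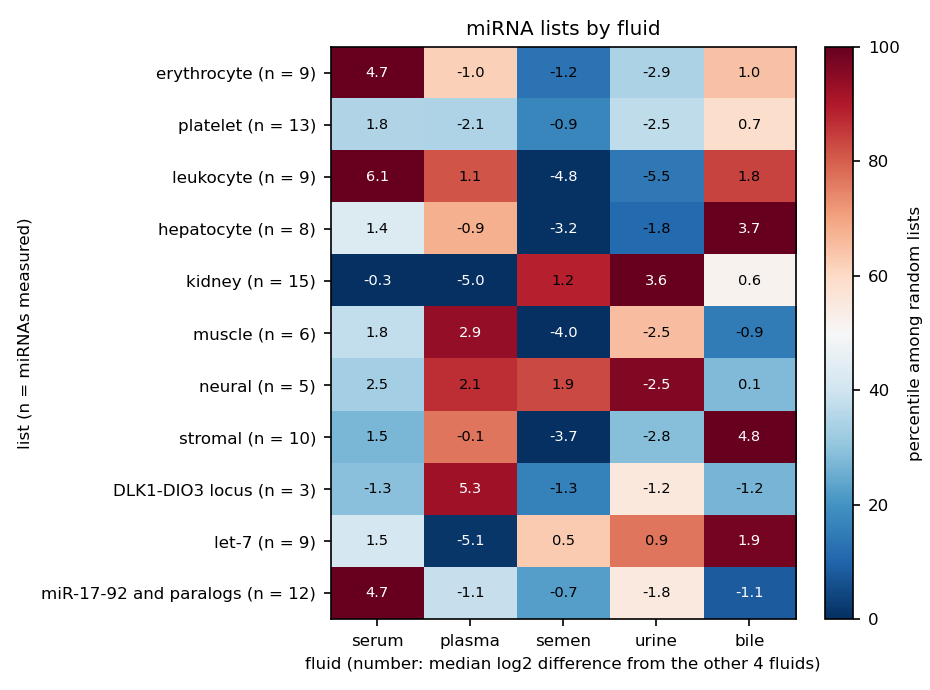
Heat map of the 11 miRNA lists with at least 3 measured members (rows, n is the number of miRNAs) in the 5 fluids (columns). Numbers give the median log2 difference from the other 4 fluids and colours the percentile among 10000 random lists; the darkest red cells include kidney in urine and stromal in bile, and the darkest blue include kidney in plasma and stromal in semen.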

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

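The alternatives chosen after the data were seen are those named as added in the account of the processing. No replicate could be left out, because each fluid has 1 library, and no paired analysis was possible because no fluid has more than 1 sample. Minimum counts of 1, 3 and 10 gave identical numbers, since the files list nothing from 1 to 9, so these settings tested nothing. Thinning to 26522 counts left 124 miRNAs in serum, 84 in plasma, 91 in semen and 99 in bile at 3 counts, a lower minimum than the 10 behind the 84 of urine. With counts under 10 also set to 0, it left 91 in serum, 50 in plasma, 61 in semen and 63 in bile. The core of 67 became 40 and 23 under these settings, and 104 without urine. Summing arms and copies moved the top-10 share to 93.6% in plasma, 89.3% in semen, 78.8% in urine and 84.5% in bile. Without the filter on low counts rho was 0.78 for serum and plasma and 0.58 for plasma and semen, with miRNAs at 0 in every library then included.

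The number of fluid-enriched miRNAs depended on the scaling and on the urine library. In serum, 13 became 7 with TMM, 5 with DESeq2 size factors, 30 at a ratio of 2, 25 with a floor of 3 counts and 29 without urine. In plasma, 7 became 25 with TMM, 23 with DESeq2, 12 without the most abundant miRNA, 12 at a ratio of 2, 20 on the authors' RPM and 16 without urine. In semen, 2 became 0 after thinning, 19 on the authors' RPM and 8 without urine. In urine, 7 became 4 with TMM, 16 at 10 counts and without a minimum, and 0 on the authors' RPM. In bile, 4 became 9 at a ratio of 2, 13 on the authors' RPM and 11 without urine. Without the plasma library no number moved by more than 1.5 times.

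Named ratios reversed in 6 cases. On the authors' RPM, urine came to 0.47 times the next fluid for miR-204, 0.70 for miR-363, 0.18 for miR-30a-5p, 0.14 for miR-30a-3p and 0.17 for miR-206, because the urine total is mostly other reads. With DESeq2 size factors miR-122 in bile came to 0.80 times plasma. For serum against plasma, miRNAs higher in plasma numbered 52 with TMM, 52 with DESeq2, 8 after thinning and 45 with the plasma-enriched miRNAs left out of both totals. Those higher in serum numbered 34, 34, 32 and 35 in the same order, and 146 at 10 counts. The 15 combinations of list and fluid past the percentile range numbered 11 to 16 under the 9 alternatives, of which those that rescale a library move a list and its random lists together and test the percentile weakly. Apart from the effects of depth, arithmetic and total stated here, the cause was not tested. Depth limits urine most: a miRNA under 377 CPM is not listed there.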

Other observations

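All tests in this part, and the miRNAs named in its opening paragraphs, were chosen after their results had been seen, except those of urine depth, of plasma composition and of a general excess of the minor arm, and in the last the removal of precursors hidden by the minimum count was also chosen afterwards.

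The share of the 2 arms of a precursor within a library does not depend on how libraries are scaled, and it differed between fluids. The 5p arm took 6.76% of miR-361 reads in plasma (95% interval 3.75 to 11.1), 31.5% in serum (27.0 to 36.3), 35.1% in semen (31.2 to 39.2) and 77.1% in bile (71.1 to 82.3). For miR-142, a leukocyte miRNA, it took 42.4% in plasma (36.2 to 48.9), 66.0% in serum (62.5 to 69.4) and 86.4% in bile (80.9 to 90.9). For miR-423 it took 99.0% in plasma, 90.1% in bile, 81.1% in serum and 64.7% in semen, with intervals that did not overlap. miR-28-5p took 20.7% of both arms in semen and 3.35% to 5.41% in serum, plasma and bile. Counts under 10 are listed as 0, which lowers the share of a scarce arm.

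The listed split between closely related miRNAs also differed between fluids. miR-192 and miR-215, which share a seed, split 30.7% to miR-192 in serum (30.1 to 31.3), 58.6% in plasma (57.5 to 59.7) and 99.8% in bile, and miR-215 was listed at 0 in semen and urine beside 269 and 371 counts of miR-192. The other pairs have nearly the same sequence. How reads were assigned was not checked for any pair here, so all these splits, that of miR-192 and miR-215 included, are uncertain. miR-10b took 72.2% of the sum with miR-10a-5p in urine (70.8 to 73.5), 48.3% in semen and 32.7% in bile. miR-199b-3p took 18.6% of the sum with miR-199a-3p in bile and was listed at 0 in the other 4 fluids. miR-378b-3p took 2.43% to 6.95% of the sum with miR-378 over the 5 fluids.

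Plasma was filled by miR-378, miR-320 and miR-423-5p, at 83.9% of its counts. The scaling of the libraries is argued against, but mainly by the authors' RPM. The lowest plasma to serum ratio of the 3 was 11.5 in CPM and 16.1 over 5 other scalings. Leaving abundant plasma miRNAs out of the totals raises that ratio by arithmetic. TMM and DESeq2 size factors also made the plasma library smaller against serum, which raised the ratio to 113 and 117. All those settings therefore tested little. On the authors' RPM, which leaves none out, the lowest ratio was 41.2, but which reads that total counts is not given. Red blood cell contents in the plasma sample are argued against as the source of its excess over serum on the authors' RPM, and less clearly with TMM or DESeq2 size factors. The erythrocyte list came to 0.22 times its serum level on the authors' RPM. With TMM and DESeq2 size factors serum exceeded plasma by 1.65 and 1.59 times, less than 2-fold, and 2 of the 9 members were highest in plasma. Serum held the most of this list of all fluids, so the comparison cannot exclude red blood cell contents in plasma as such. A single library preparation that differs from the others cannot be told apart from a property of plasma exosomes, because there is 1 plasma library. The low CPM of most other miRNAs in plasma may follow from the share that miR-378, miR-320 and miR-423-5p take, but the test could not decide this. With the 7 plasma-enriched miRNAs left out of both totals the median log2 ratio of plasma to serum went from -2.77 to 0.19. These 7 were chosen as high in plasma, so leaving them out raises every remaining ratio by arithmetic, which forces the change. On the authors' RPM a difference of -0.93 stayed.

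Urine listed 84 miRNAs against 161 to 180 in the other fluids. A smaller miRNA total in the urine library may account for this, since the other libraries, thinned to its total with counts under 10 set to 0, listed at most 1.08 times as many. The order turned for 3 of the 4: medians were 50 in plasma (45 to 57 over the draws), 61 in semen (54 to 67) and 63 in bile (59 to 68), under the 84 of urine, and 91 in serum (86 to 95). At equal totals urine thus did not list the fewest miRNAs. A biological difference between fluids was not tested, and why miRNAs took 0.246% of that library stays open.

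miR-148a-5p took 16.8% of the reads of its precursor in plasma (16.3 to 17.4), against 0.243% in serum, 0.305% in semen, 0.0270% in bile and a listed 0 beside 4401 counts of the 3p arm in urine. The scaling of the libraries cannot move this share, and its lower bound in plasma, 16.3%, lay above the highest upper bound elsewhere, 0.387%, with the listed 0 of urine taken as 9 reads. The minor arm was taken as the scarcer arm in serum, a choice that tilts the count below towards plasma. For miR-133a, miR-143 and miR-17 that arm was listed at 0 in serum, so its share could not be lower in plasma. Of 27 other precursors, 7 had the minor arm at 0 in both serum and plasma and 2 had too few reads in plasma to list it at the serum share, and it was higher in plasma in 10 of the remaining 18, or 55.6% (30.8 to 78.5). A general excess of the minor arm in plasma, predicted to give 3 of 4, stays open, because the interval reaches that share, while counting those 2 as lower gave 50% of 20 (27.2 to 72.8), below it. Whether a second plasma library would show it was not tested, and no biological explanation was tested.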
